A study of Bacillus subtilis subsp. subtilis str. 168 with 10 samples.

How the data were processed

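RNA of Bacillus subtilis 168 was measured on 10 two-colour Agilent arrays, 2 biological replicates at each of 5 time points of a glucose starvation course. Per the labels' protocols, cells grew at 37 °C in minimal medium with 0.05% glucose and 0.05% malate, and starvation followed growth to an OD500 of 1.0. RNA was isolated after mechanical disruption with acid phenol, and 10 µg of total RNA with spike-in RNA was copied from random primers. The sample carried Cy5 and the reference pool Cy3, per the labels.

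Per the submitters' processing notes, arrays were read with Agilent Feature Extraction 10.5. The gene table holds ratios which, per the file headers, are error-weighted averages of the probe ratios of each annotated gene, made with Rosetta Resolver 7.2.1. Its normalization between arrays is not stated. It holds 4105 genes with ratios from 0.00083 to 20.5, of which those above 10 exceed what an equal pool of 10 samples allows on a common scale, and 36 values in 9 genes are exactly 1. The deposited series matrix holds log10 ratios of 41882 array features, which carry numbers and no gene names. Its log base and direction are not stated and were set by comparison with the gene table. The 45 correlations between pairs of arrays in the 2 tables correlated with r = 0.998, and the slopes of its quantiles on those of the log10 gene ratios lay between 0.812 and 0.988. Neither value can show the direction, since both would be positive with all signs reversed. The skew can, and it was negative in every column, from -2.05 to -0.62 for features and from -2.47 to -0.34 for log10 gene ratios. Its column medians were 0.0593, 0.00271, 0.0359, 0.037 and 0 for replicate 1 and 0.0451, 0, 0.0432, 0.0306 and 0.0218 for replicate 2, from exponential growth to 120 min, and how the columns were scaled or centred is not known.

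The gene table was used for every comparison after taking log2 of the deposited ratios, with no further scaling. A linear model with one mean per time point was fitted to all 10 arrays with limma 3.58.1 in R 4.3.3 and moderated with eBayes, which left 5 residual degrees of freedom and added 3.24 prior ones. The comparisons were each later time against exponential growth and each time against the one before it, 7 in all, and an F test over the 4 comparisons against exponential growth. P values were adjusted by the method of Benjamini and Hochberg within each comparison, and genes with an adjusted p under 0.05 were called changed. Counts adjusted over a list alone repeat this adjustment with only the genes of that list. The same model on the 41401 features whose values varied called 16052, 26467, 26588 and 28734 features changed at 0, 30, 60 and 120 min against exponential growth, and 19652, 3045 and 7675 between successive times.

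The 40 gene lists were written from general knowledge before the data were examined, and 764 of their 770 members were measured, 53 of them matched by a current gene symbol only. Lists were tested with camera at a preset correlation between genes of 0.01 and adjusted over the lists of each comparison. The test was repeated with an estimated correlation and with fry. Gene names follow the gene table, with current symbols from the RefSeq annotation of assembly ASM904v1, to which 4037 of 4105 genes matched by locus tag. Genes named in the text came from a rule fixed in advance, except for 5 of the late sporulation genes of the closing section, cotX, cotV, yjcC, cgeC and sspG, which were chosen after their values were seen. The rule took the 10 largest changes in each direction against exponential growth, the 4 largest in each direction between successive times, up to 4 members per list, and a list of global regulators.

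The fit and the list test were tested on simulated data, with 4105 genes, 200 changed genes and 20 simulations. Each gene was drawn around its mean over all 10 arrays, with its residual spread from the fit, alike at every time point. Changes were added at the transition phase and tested against exponential growth. For that comparison 31.0% of genes changed 1.5-fold, 69.7% of those changed 2-fold, 93.4% of those changed 4-fold and 98.0% of those changed 8-fold were called in the right direction, and 5.13% of calls were unchanged genes. On the measured arrays 2425 genes were called changed in this comparison, many more than the 200 simulated. The cutoff set by the adjustment depends on that share, so these rates need not hold for the measured comparison. For the list test, all genes of a given list were raised 2-fold in each simulation. This shifted list was called in 20 of 20 simulations, and 0.259% of the tests of lists left alone were called. Smaller shifts and lists changed only in part were not simulated. The simulated genes varied independently of each other. The rate of list calls therefore does not cover lists whose genes vary together, as in the measured arrays. Alternatives tried were a replicate block, leaving out each array, centring, quantile normalization, a variance trend with robust moderation (for camera only the trend in the variance), array weights, fits of only the 2 time points compared, a stricter threshold of 0.01, and leaving out genes holding a value of exactly 1. In some of these alternative fits limma met genes with a variance of 0 and set it slightly above 0. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.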

Results

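RNA levels of Bacillus subtilis 168 were followed through glucose starvation in a minimal medium that held glucose and L-malate at 0.05% each. Samples came from 5 time points, namely exponential growth, the transition phase (0 min), and 30, 60 and 120 min after it. Each time point had 2 biological replicates, which gave 10 two-colour arrays. On every array the sample, labelled with Cy5, was compared with a reference labelled with Cy3, per the labels a pool of equal RNA amounts of all 10 samples. The values were ratios of sample over pool for 4105 genes. The mean of a gene's 10 ratios had a median of 1.13 over genes, so a ratio of 1 is not the average of the course. A ratio over an equal pool of 10 samples cannot exceed 10 on a common scale, yet 37 genes had ratios above 10, up to 20.5, all at 120 min. The ratios are therefore not exact shares of such a pool, and the cause was not tested. The median ratio of an array lay between 0.860 and 1.197. Across genes, which are not independent replicates, the log2 ratios of replicates correlated with r between 0.93 and 0.98. The lowest correlation between any pair of arrays was -0.50. The direction of the ratios was kept as given because the dyes are stated and because time points measured against their own pool can oppose each other. The number of arrays limits the precision of every value. Signals and backgrounds are not given in the sources used here, so the lowest ratios may rest on dim signals.

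Nearly the whole transcriptome moved over the course. With limma's moderated F test, 3842 of 4105 genes (93.6%) differed among the 5 time points. Against exponential growth the number of changed genes went from 2425 at the transition to 3262 at 30 min, 3294 at 60 min and 3385 at 120 min. Between successive times it was 2800 from the transition to 30 min, 1072 from 30 to 60 min and 1515 from 60 to 120 min. All values below are log2 changes with the standard error (SE) of the fit, from 2 arrays per time point, and the median SE over genes was 0.18. The spread of a gene was pooled over the 5 time points, so its SE is the same in every comparison. Replicates differed more at 120 min (SD of log2 0.54) than at the other times (0.30 to 0.35). The SEs and p values of comparisons with 120 min may therefore be too small. Relative to exponential growth the median log2 change of all genes was -0.09, -0.16, -0.30 and -0.45 at 0, 30, 60 and 120 min. Setting every array's median to 0 takes out shifts of -0.22, -0.20, -0.25 and -0.44 at these times and of 0.02, -0.05 and -0.18 between successive times. Changes of gene lists were tested with camera, which compares a list with the other genes of the same arrays and is therefore relative to this shift. None of the list calls passed when camera estimated the correlation between genes from the arrays, and that p is given beside each call.

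**Figure D1:**
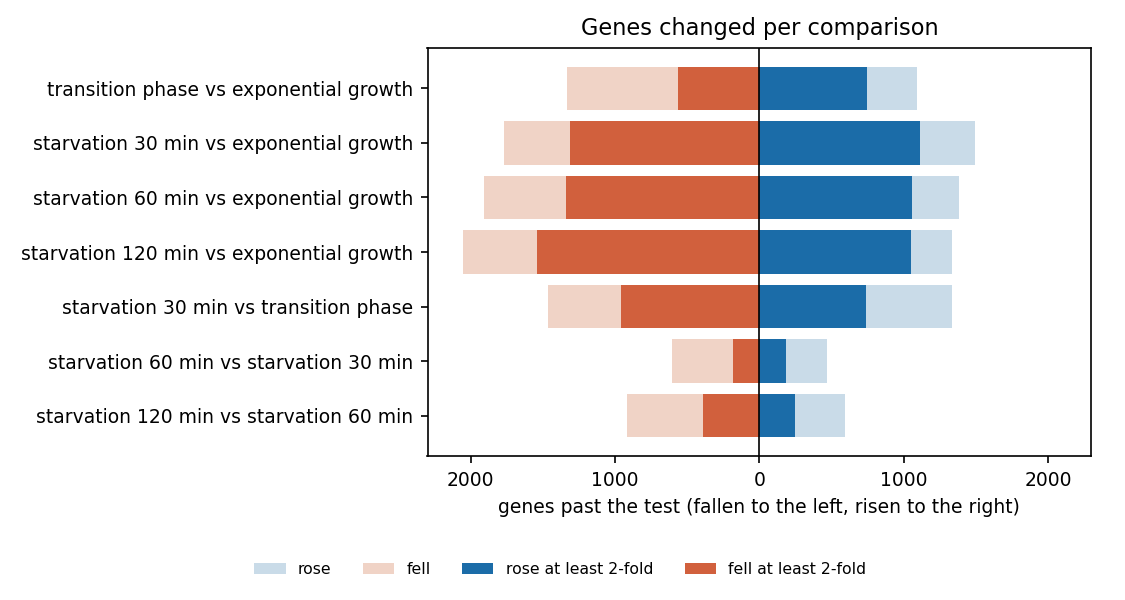
Number of genes that rose (bars to the right) or fell (bars to the left) in each of the 7 comparisons at an adjusted p under 0.05. The dark part of each bar is the genes changed at least 2-fold, 748 upward and 566 downward at the transition and 1051 upward and 1544 downward at 120 min.

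At the transition phase, genes for the uptake and use of sugars other than glucose showed the largest increases. The ribose uptake gene rbsA (BSU35940) rose 329.8-fold, a log2 change of 8.37 ± 0.23, and rbsC, rbsB and rbsD of the same operon changed by 7.96 ± 0.20, 7.67 ± 0.23 and 7.30 ± 0.22. The operon for oligomeric beta-glucosides also rose, with 8.21 ± 0.26 for licC, 7.04 ± 0.20 for licB, 6.97 ± 0.15 for licH and 6.85 ± 0.24 for licA. The C4-dicarboxylate transporter gene dctP rose by 6.99 ± 0.44, and yngI (ldeI) by 6.99 ± 0.24. In the other direction, the malate transporter gene maeN (BSU31580) changed by -4.63 ± 0.20 and ywkA, the malic enzyme gene maeA of current annotation, by -4.29 ± 0.48. The largest decrease was that of ywbH (cidA), at -5.47 ± 0.19, followed by purK at -4.96 ± 0.15, purE at -4.94 ± 0.26 and ywbG (cidB) at -4.87 ± 0.40.

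Of 66 measured genes for alternative carbon sources under control of the catabolite repressor CcpA, 61 rose, 1 fell and 4 did not pass, and the counts adjusted over the list alone were 61 and 1. Their median change was 3.67, or 12.7-fold (camera adjusted p = 2.3e-25, and adjusted p = 0.29 with an estimated correlation). All 14 genes for the use of myo-inositol rose, also when adjusted over the list alone, with 4.81 ± 0.12 for the transporter gene ydjK (iolT) and 4.42 ± 0.19 for iolE (camera adjusted p = 1.5e-09, and adjusted p = 0.45 with an estimated correlation). In the list for acetoin and acetate use 5 of 9 genes rose, 5 of them adjusted over the list alone, among them acoR at 4.94 ± 0.13 and acsA at 3.31 ± 0.14 (camera adjusted p = 0.0015, and adjusted p = 0.52 with an estimated correlation). The tricarboxylic acid cycle, which oxidises acetyl groups, had 11 of 14 genes up and 1 down, with the same counts adjusted over the list alone (camera adjusted p = 2.8e-04, and adjusted p = 0.45 with an estimated correlation). Its examples are citZ at 2.19 ± 0.17, sdhA at 1.80 ± 0.13, odhB at 1.72 ± 0.23 and sucC at 1.70 ± 0.22. All 6 overflow genes fell, also adjusted over the list alone, led by the acetate kinase gene ackA at -3.04 ± 0.16 (camera adjusted p = 0.0056, and adjusted p = 0.45 with an estimated correlation). Of 11 genes for fatty acid degradation 10 rose, 10 adjusted over the list alone, with 3.66 ± 0.26 for ywjF (fadF) and 3.43 ± 0.36 for yusL (fadN) (camera adjusted p = 6.7e-05, and adjusted p = 0.52 with an estimated correlation).

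Of 50 ribosomal protein genes 47 fell, 48 adjusted over the list alone, with a median change of -1.04 (camera adjusted p = 9.2e-11, and adjusted p = 0.52 with an estimated correlation). In this list rplW and rplD changed by -1.97 ± 0.18 and -1.92 ± 0.18. All 19 genes for purine synthesis and uptake fell, also adjusted over the list alone, among them pbuG at -4.68 ± 0.23 and purB at -3.87 ± 0.20 (camera adjusted p = 3.9e-09, and adjusted p = 0.45 with an estimated correlation). In pyrimidine synthesis 5 of 10 genes fell and 5 did not pass, 5 adjusted over the list alone, with pyrR, the first gene of the operon, at -4.39 ± 0.21 and pyrP at -3.54 ± 0.18 (camera adjusted p = 0.052, and adjusted p = 0.52 with an estimated correlation). The list for glucose uptake and glycolysis also holds the regulator gene cggR and pyruvate dehydrogenase genes. It held 8 fallen and 1 risen gene of 17, 7 and 1 adjusted over the list alone, with cggR at -3.81 ± 0.40 and pdhB at -1.69 ± 0.36 (camera adjusted p = 0.091, and adjusted p = 0.63 with an estimated correlation). In the short gluconeogenesis list, which also holds speD, pckA changed by -1.08 ± 0.24 and speD by -1.36 ± 0.18, while gapB changed by 0.79 ± 0.25.

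Sporulation genes were already up at this time. In the list of mother cell genes under SigE 26 of 28 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.0e-13, and adjusted p = 0.38 with an estimated correlation). Its members mmgB, mmgA and mmgC changed by 6.70 ± 0.23, 6.08 ± 0.29 and 5.85 ± 0.15. Of the forespore and late genes 22 of 31 rose and 2 fell, also adjusted over the list alone, with 5.03 ± 0.35 for the small spore protein gene sspB and 3.40 ± 0.22 for spoIIQ (camera adjusted p = 3.0e-05, and adjusted p = 0.52 with an estimated correlation). Genes for genetic competence rose in 18 of 27 cases and fell in 2, with the same counts adjusted over the list alone, such as comGD at 1.82 ± 0.27 and comGA at 1.82 ± 0.23 (camera adjusted p = 3.8e-04, and adjusted p = 0.52 with an estimated correlation). For the 40 genes of the general stress regulon of SigB, 9 rose and 1 fell over all genes tested while 0 rose and 0 fell when adjusted over the list alone, with a median of 0.77 (camera adjusted p = 0.011, and adjusted p = 0.74 with an estimated correlation).

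Over all 4105 genes, 1089 rose and 1336 fell at the transition, a share risen of 44.9%, which became 57.8% with every array centred on its median. Of these, 204 rose and 21 fell at least 8-fold. With quantile normalization between arrays the median of the SigB list turned to -0.32, gapB turned to -1.29 and was called as fallen, and the calls for fatty acid degradation (adjusted p = 0.35) and late sporulation (adjusted p = 0.61) were lost.

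**Figure D2:**
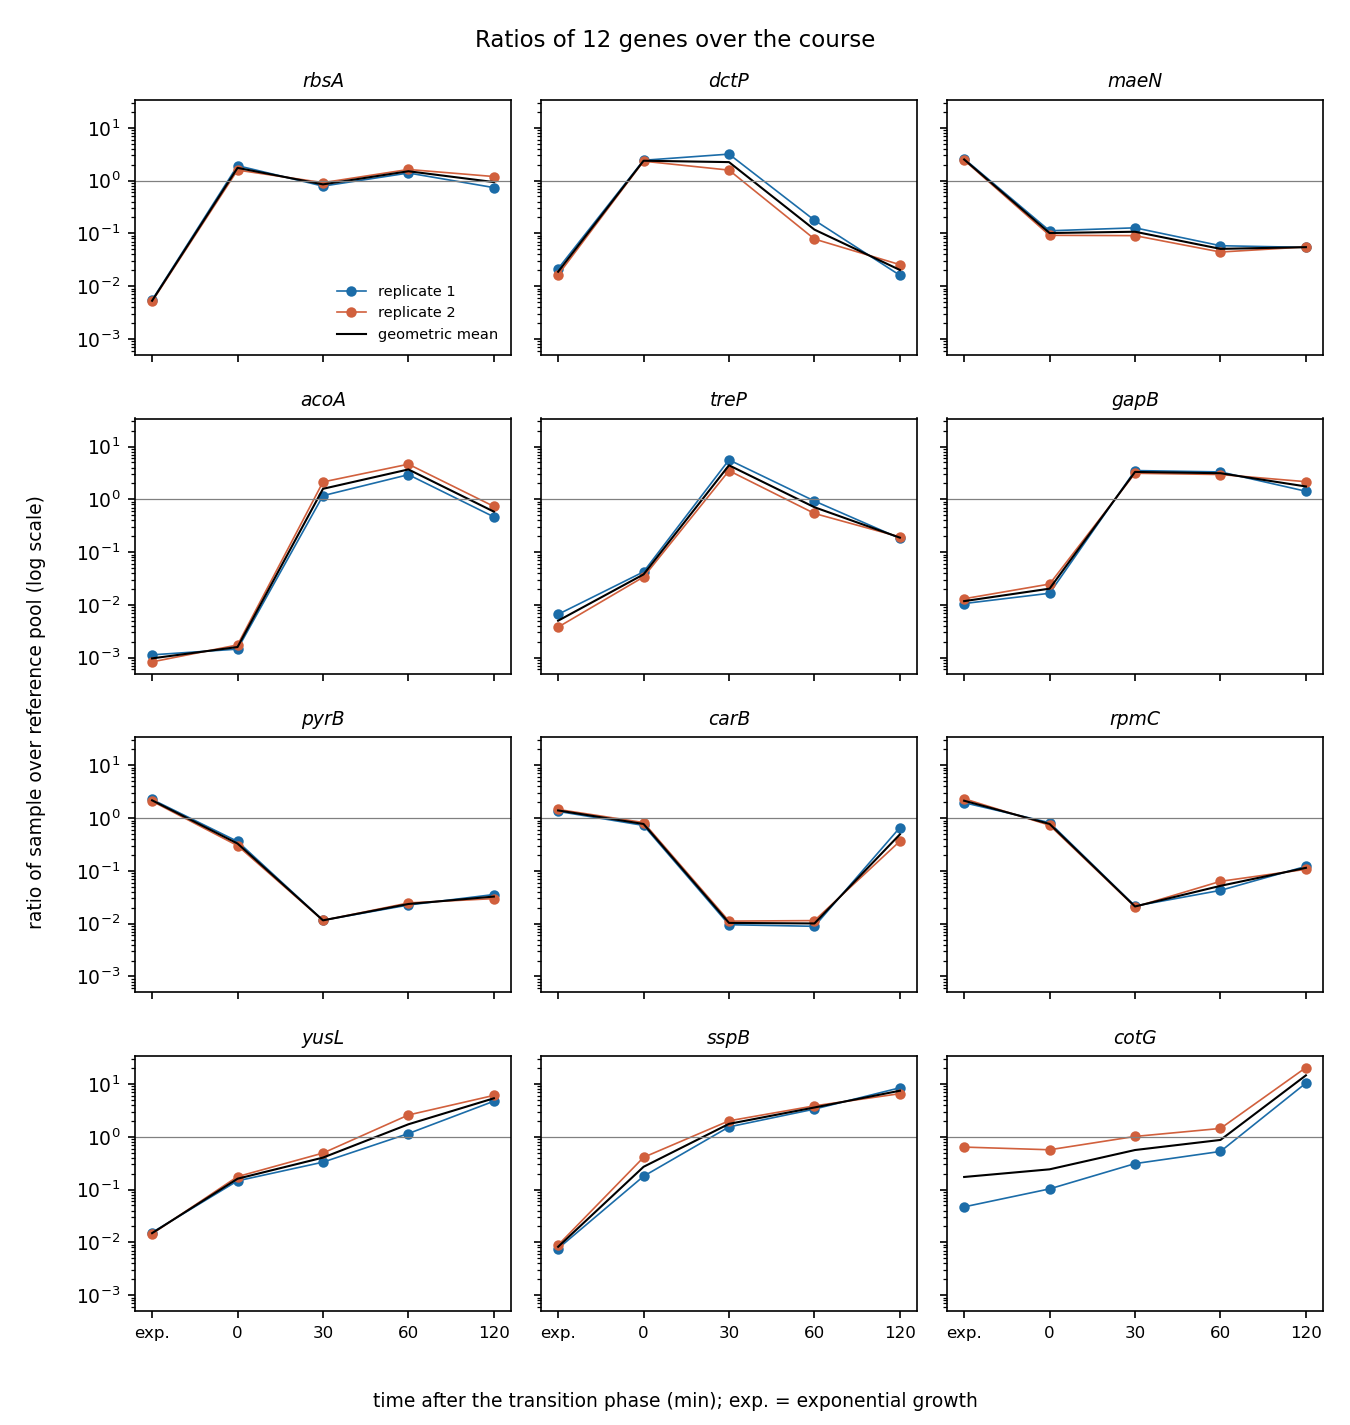
Ratios of sample over reference pool on a log scale for 12 genes at the 5 time points, with replicates 1 and 2 as points and their geometric mean as a black line. The ribose gene rbsA rose by 0 min, acoA, treP and gapB mostly between 0 and 30 min, and the spore gene cotG had ratios of 10.4 and 20.5 at 120 min, above the limit of 10 for an equal pool.

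At 30 min of starvation the genes for acetoin breakdown stood far above their level during growth. The acetoin dehydrogenase gene acoA (BSU08060) rose 1634-fold, a log2 change of 10.67 ± 0.36, with 9.22 ± 0.36 for acoC, 9.17 ± 0.29 for acoB and 8.61 ± 0.34 for acoL. Genes for trehalose uptake and cleavage were also high, with 9.78 ± 0.35 for treP and 8.95 ± 0.36 for treA. The gluconeogenic glyceraldehyde phosphate dehydrogenase gene gapB rose by 8.14 ± 0.25, and the phosphoenolpyruvate carboxykinase gene pckA by 6.36 ± 0.24. The largest decreases included genes of pyrimidine and arginine synthesis and of ribosomal proteins, with -7.56 ± 0.15 for pyrB (BSU15490), -7.16 ± 0.15 for pyrC, -7.08 ± 0.27 for carB and -6.66 ± 0.20 for rpmC.

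All 9 genes for acetoin and acetate use rose, also adjusted over the list alone, with a median of 6.40 (camera adjusted p = 7.6e-05, and adjusted p = 0.47 with an estimated correlation). Of the 66 genes for alternative carbon sources 58 rose and 2 fell, 59 and 2 adjusted over the list alone, with manP, for mannose uptake, at 7.67 ± 0.41 (camera adjusted p = 6.7e-15, and adjusted p = 0.47 with an estimated correlation). All 4 genes of the gluconeogenesis list, speD among them, rose, also adjusted over the list alone (camera adjusted p = 0.014, and adjusted p = 0.47 with an estimated correlation). Glucose uptake and glycolysis went the other way, with 16 of 17 genes fallen and 1 risen, the same counts as adjusted over the list alone (camera adjusted p = 3.4e-04, and adjusted p = 0.47 with an estimated correlation). The glucose transporter gene ptsG changed by -4.55 ± 0.21, ptsI by -3.19 ± 0.20 and the pyruvate dehydrogenase gene pdhB by -3.29 ± 0.36. In the tricarboxylic acid cycle 4 of 14 genes stood above growth and 3 below, the same as adjusted over the list alone, with sdhB at 1.40 ± 0.13 and citZ at 1.14 ± 0.17.

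All 50 ribosomal protein genes fell, also adjusted over the list alone, with a median of -4.37, or 20.7-fold lower (camera adjusted p = 4.5e-15, and adjusted p = 0.47 with an estimated correlation). Among them were rplW at -6.49 ± 0.18, rplP at -6.38 ± 0.16 and rpsQ at -6.31 ± 0.25. All 10 pyrimidine genes fell, also adjusted over the list alone, with pyrAA at -6.79 ± 0.16 (camera adjusted p = 2.2e-05, and adjusted p = 0.47 with an estimated correlation). All 9 arginine synthesis genes fell as well, also adjusted over the list alone, with argD at -6.22 ± 0.26 (camera adjusted p = 2.3e-04, and adjusted p = 0.47 with an estimated correlation). In purine synthesis 18 of 19 genes fell and 1 rose, with the same counts adjusted over the list alone, such as the xanthine uptake gene pbuX at -6.28 ± 0.22 and purN at -5.99 ± 0.17 (camera adjusted p = 9.8e-07, and adjusted p = 0.47 with an estimated correlation). All 9 ATP synthase genes fell, also adjusted over the list alone, with atpG at -3.67 ± 0.23 and atpD at -3.59 ± 0.23 (camera adjusted p = 0.0026, and adjusted p = 0.47 with an estimated correlation). Fatty acid synthesis had 11 of 13 genes down, 11 adjusted over the list alone, with fabD at -3.18 ± 0.22 (camera adjusted p = 0.0031, and adjusted p = 0.47 with an estimated correlation).

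Motility genes mostly fell. Of 40 flagellar and chemotaxis genes 28 fell, 3 rose and 9 did not pass, 28 and 3 adjusted over the list alone (camera adjusted p = 1.6e-04, and adjusted p = 0.47 with an estimated correlation). The gene flhF changed by -5.95 ± 0.18 and cheB by -5.87 ± 0.19. The SigB list had 30 of 40 genes up and 1 down, 29 and 1 adjusted over the list alone (camera adjusted p = 1.6e-04, and adjusted p = 0.61 with an estimated correlation). Examples are gsiB at 5.54 ± 0.50, nhaX at 5.35 ± 0.50 and yflT at 5.20 ± 0.55. The mother cell list had 26 of 28 genes up, 26 adjusted over the list alone, with mmgB at 8.24 ± 0.23 (camera adjusted p = 6.0e-09, and adjusted p = 0.47 with an estimated correlation). The forespore and late list had 25 of 31 up, 25 adjusted over the list alone, with sspB at 7.74 ± 0.35 and sspC at 6.92 ± 0.32 (camera adjusted p = 2.0e-06, and adjusted p = 0.47 with an estimated correlation). In the list for sporulation initiation, rapA and phrA, which encode a phosphatase of the phosphorelay and its inhibitor peptide, rose by 5.50 ± 0.24 and 5.15 ± 0.35. Over all genes 1494 rose and 1768 fell at 30 min, of which 406 and 273 by at least 8-fold. With every array centred on its median 1674 rose and 1601 fell.

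After 60 min of starvation the same acetoin operon had the largest increases, with 11.89 ± 0.36 for acoA, 10.81 ± 0.36 for acoC, 10.59 ± 0.29 for acoB and 10.03 ± 0.34 for acoL against exponential growth. Also among the 10 largest increases were sspB, a gene for a small DNA-binding spore protein, at 8.77 ± 0.35, and the maltodextrin uptake genes yvdG (mdxE, BSU34610), yvdH and yvdI at 8.69 ± 0.18, 8.61 ± 0.26 and 8.31 ± 0.23. The maltose genes malA and malP rose by 8.24 ± 0.16 and 8.17 ± 0.14. The largest decreases included carB at -7.12 ± 0.27, pbuX at -6.92 ± 0.22, pyrB at -6.53 ± 0.15 and argD at -6.41 ± 0.26. The genes yurO and yurN, of an operon for the use of fructosamines, changed by -6.32 ± 0.34 and -5.93 ± 0.31.

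The SigB regulon had its highest count of risen genes here, with 37 of 40 members up and none down, 38 adjusted over the list alone (camera adjusted p = 4.0e-07, and adjusted p = 0.50 with an estimated correlation). Its median was 2.81, or 7-fold, with nhaX at 6.21 ± 0.50, gsiB at 4.92 ± 0.50 and sigB itself, the gene of the sigma factor, at 1.25 ± 0.42. All 11 genes of fatty acid degradation were up, also adjusted over the list alone, with yusL (fadN) at 6.85 ± 0.36 and yusK (fadA) at 6.60 ± 0.40 (camera adjusted p = 1.4e-05, and adjusted p = 0.44 with an estimated correlation). Of the alternative carbon genes 57 of 66 were up and 3 down, also adjusted over the list alone (camera adjusted p = 1.9e-15, and adjusted p = 0.44 with an estimated correlation). Mother cell and late sporulation lists had 26 of 28 and 26 of 31 genes up, both also when adjusted over the list alone. For the mother cell list the camera adjusted p = 1.9e-09, and adjusted p = 0.44 with an estimated correlation. For the late list the camera adjusted p = 1.8e-08, and adjusted p = 0.44 with an estimated correlation, and spoVAC and spoVAA, for dipicolinic acid transport, changed by 5.52 ± 0.27 and 5.48 ± 0.35.

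All 50 ribosomal protein genes were down, also adjusted over the list alone, with a median of -3.76 (camera adjusted p = 3.8e-13, and adjusted p = 0.44 with an estimated correlation), for example rpmC at -5.36 ± 0.20. The lists for purine, pyrimidine and arginine synthesis were down in all of their 19, 10 and 9 genes, also adjusted over the list alone. The camera adjusted p = 4.0e-07, and adjusted p = 0.44 with an estimated correlation, for purines, 3.1e-05 and 0.44 in the same order for pyrimidines, and 2.1e-04 and 0.44 for arginine. Of the flagellar genes 35 of 40 were down, 35 adjusted over the list alone, with cheB at -5.51 ± 0.19 (camera adjusted p = 7.5e-06, and adjusted p = 0.44 with an estimated correlation). The biofilm matrix list, which holds eps operon genes and yuaB (bslA), fell in 14 of 15 cases, 14 adjusted over the list alone, with yvfC (epsL) at -3.44 ± 0.33 (camera adjusted p = 0.0013, and adjusted p = 0.50 with an estimated correlation). The transition state regulator gene abrB rose by 1.94 ± 0.20. Over all genes 1386 rose and 1908 fell at 60 min, of which 454 and 241 by at least 8-fold. With every array centred on its median 1596 rose and 1633 fell.

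At 120 min the spore gene sspB (BSU09750) had the largest increase against exponential growth. It rose 906-fold, a log2 change of 9.82 ± 0.35, with 8.49 ± 0.29 for sspJ and 8.38 ± 0.49 for cotY, a gene of the spore crust. Fatty acid breakdown was also high, with 8.49 ± 0.36 for yusL (fadN) and 8.43 ± 0.40 for yusK (fadA), and the arabinanase gene abnA with 8.63 ± 0.22. The acetoin genes acoA and acoC were still up by 9.24 ± 0.36 and 8.48 ± 0.36, and yhfH, of unknown function, by 8.79 ± 0.30. The largest decreases were those of yurP (frlB), at -7.24 ± 0.52, of the adjacent genes yybK, yybL and yybJ at -6.99 ± 0.23, -6.74 ± 0.30 and -6.61 ± 0.16, and of the methionine synthase gene metE at -6.40 ± 0.18.

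Of the forespore and late sporulation genes 30 of 31 were up and 1 down, also adjusted over the list alone, with a median of 4.49 (camera adjusted p = 2.7e-10, and adjusted p = 0.47 with an estimated correlation). The dipicolinic acid synthesis genes spoVFA and spoVFB changed by 7.37 ± 0.48 and 6.70 ± 0.49. The mother cell list had 21 of 28 genes up and 2 down, also adjusted over the list alone (camera adjusted p = 8.9e-06, and adjusted p = 0.47 with an estimated correlation). All 11 fatty acid degradation genes were up, also adjusted over the list alone, by a median of 64.2-fold (camera adjusted p = 2.8e-06, and adjusted p = 0.47 with an estimated correlation). Competence genes, up at the transition, were down in 26 of 27 cases, 26 adjusted over the list alone, with comGC at -3.73 ± 0.29 and the regulator gene comK at -1.51 ± 0.21 (camera adjusted p = 7.2e-05, and adjusted p = 0.47 with an estimated correlation). All 15 genes of the biofilm matrix list were down, also adjusted over the list alone, with yvfC (epsL) at -5.30 ± 0.33 (camera adjusted p = 1.1e-04, and adjusted p = 0.47 with an estimated correlation). Flagellar genes were down in 37 of 40 cases, 37 adjusted over the list alone, with fliR at -5.29 ± 0.16 (camera adjusted p = 9.6e-08, and adjusted p = 0.47 with an estimated correlation). All 17 genes of the list for glucose uptake and glycolysis were down, also adjusted over the list alone, with ptsG at -3.82 ± 0.21 (camera adjusted p = 0.0011, and adjusted p = 0.47 with an estimated correlation). All 21 aminoacyl-tRNA synthetase genes were down, also adjusted over the list alone, with pheS at -3.98 ± 0.29 and hisS at -3.91 ± 0.15 (camera adjusted p = 1.6e-05, and adjusted p = 0.47 with an estimated correlation). All 50 ribosomal protein genes remained below growth, with a median of -3.22 (camera adjusted p = 2.3e-10, and adjusted p = 0.47 with an estimated correlation).

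Of the SigB list 35 of 40 genes were up, 35 adjusted over the list alone, with a median of 2.72 (camera adjusted p = 3.0e-07, and adjusted p = 0.49 with an estimated correlation). The replicates differed here. The median log2 ratio of the list at 120 min was 1.95 in replicate 1 and 0.35 in replicate 2, and all 40 members were higher in replicate 1, 39 of them over 2-fold. Over all genes the spread of the replicate difference at 120 min was 0.54 (SD of log2), against 0.30 to 0.35 at the other times, and 29 genes were over 4-fold apart. Over all genes 1333 rose and 2052 fell at 120 min, a share risen of 39.4%, which became 50.1% with every array centred on its median. Of these, 508 rose and 322 fell at least 8-fold.

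**Figure D3:**
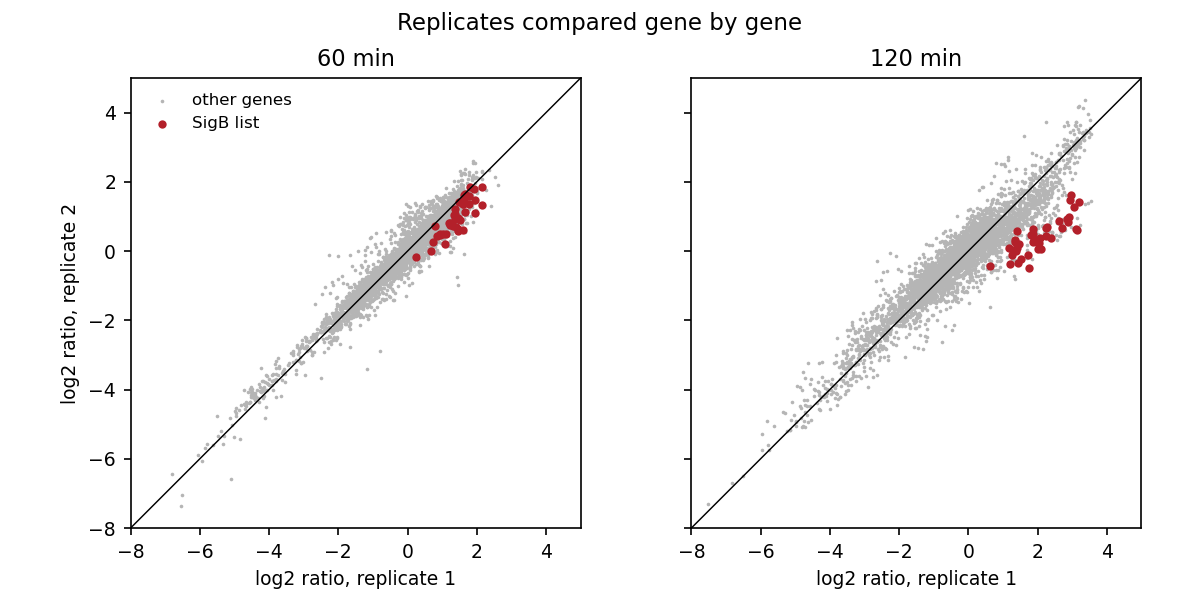
Log2 ratios of all genes in replicate 1 against replicate 2 at 60 min and at 120 min, each gene a point, with the 40 genes of the SigB list in red and the line of equal ratios in black. At 120 min all 40 red points lie on the side of replicate 1, with list medians of 1.95 and 0.35 in replicates 1 and 2.

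From the transition phase to 30 min of starvation the acetoin operon rose and ribosomal protein genes fell. The genes acoA, acoC, acoB and acoL rose by 9.96 ± 0.36, 8.62 ± 0.36, 8.61 ± 0.29 and 8.39 ± 0.34. The gluconeogenic genes pckA (BSU30560) and gapB rose by 7.44 ± 0.24 and 7.35 ± 0.25, and treP by 6.87 ± 0.35. The fructosamine genes yurN and yurO fell most, with -6.61 ± 0.31 and -6.35 ± 0.34, followed by carB at -6.23 ± 0.27 and pyrF at -6.05 ± 0.13. In the gluconeogenesis list 3 of 4 genes rose, also adjusted over the list alone (camera adjusted p = 0.0027, and adjusted p = 0.47 with an estimated correlation). Alternative carbon genes had no common direction, with 25 risen and 31 fallen of 66, 26 and 31 adjusted over the list alone. Among those that rose were treA at 6.71 ± 0.36 and malA at 4.95 ± 0.16.

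All 50 ribosomal protein genes fell in these 30 min, also adjusted over the list alone, by a median of -3.45 (camera adjusted p = 8.8e-19, and adjusted p = 0.47 with an estimated correlation), with rpsQ at -5.27 ± 0.25. The list for glucose uptake and glycolysis fell in 15 of 17 genes, 15 adjusted over the list alone, with ptsG at -4.80 ± 0.21 (camera adjusted p = 2.3e-04, and adjusted p = 0.47 with an estimated correlation). The tricarboxylic acid cycle fell in 11 of 14, 11 adjusted over the list alone, with sucC at -2.43 ± 0.22 and odhA at -2.18 ± 0.17 (camera adjusted p = 0.0019, and adjusted p = 0.47 with an estimated correlation). Pyrimidine synthesis had 9 of 10 genes down and 1 up, 9 and 1 adjusted over the list alone (camera adjusted p = 3.7e-05, and adjusted p = 0.47 with an estimated correlation). Of the competence list 22 of 27 genes fell, 22 adjusted over the list alone, with comGG at -3.71 ± 0.39 (camera adjusted p = 7.2e-05, and adjusted p = 0.47 with an estimated correlation). Of the biofilm matrix list 13 of 15 genes fell, 13 adjusted over the list alone, with yvfF (epsO) at -3.36 ± 0.17 (camera adjusted p = 3.2e-04, and adjusted p = 0.56 with an estimated correlation). Late sporulation genes rose in 23 of 31 cases, 23 adjusted over the list alone, with sspB at 2.70 ± 0.35 (camera adjusted p = 2.4e-05, and adjusted p = 0.54 with an estimated correlation). SigB genes rose in 22 of 40 cases, 22 adjusted over the list alone, with gsiB at 4.49 ± 0.50 and ydaD at 3.68 ± 0.67 (camera adjusted p = 9.6e-04, and adjusted p = 0.73 with an estimated correlation). Over all genes 1332 rose and 1468 fell.

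From 30 to 60 min the changes were smaller. The plipastatin synthetase genes ppsD (BSU18310), ppsC and ppsE rose by 2.96 ± 0.29, 2.69 ± 0.18 and 2.64 ± 0.32, and pgcM, of the maltodextrin operon, by 2.70 ± 0.28. The transporter gene dctP fell by a log2 change of -4.25 ± 0.44, and ysbA and ysbB, genes for pyruvate uptake, by -4.15 ± 0.61 and -3.76 ± 0.56. The histidine synthesis gene hisB changed by -2.89 ± 0.64. All 9 ATP synthase genes rose, also adjusted over the list alone, by a median of 1.93, with atpD and atpG at 2.03 ± 0.23 and 2.03 ± 0.23 (camera adjusted p = 1.2e-07, and adjusted p = 0.61 with an estimated correlation). Ribosomal protein genes rose in 37 of 50 cases, 37 adjusted over the list alone, by a median of 0.88, with rpsB at 1.41 ± 0.12 and rplS at 1.38 ± 0.15 (camera adjusted p = 6.3e-16, and adjusted p = 0.61 with an estimated correlation). All 11 fatty acid degradation genes rose, also adjusted over the list alone, with yusL (fadN) at 2.10 ± 0.36 and ykuF (fadH) at 1.93 ± 0.43 (camera adjusted p = 1.1e-06, and adjusted p = 0.61 with an estimated correlation). All 14 myo-inositol genes fell, also adjusted over the list alone, with mmsA (iolA) at -1.31 ± 0.14 (camera adjusted p = 1.2e-07, and adjusted p = 0.61 with an estimated correlation). Sugar genes also fell singly, with treP at -2.64 ± 0.35 and levD at -2.48 ± 0.19.

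In the SigB list 5 of 40 genes rose from 30 to 60 min and 0 when adjusted over the list alone, among them sigB at 1.46 ± 0.42 (camera adjusted p = 0.0015, and adjusted p = 0.71 with an estimated correlation). Without replicate 1 at 60 min this call was lost (adjusted p = 0.06). The biofilm matrix list fell in 9 of 15 genes, 12 adjusted over the list alone, with yveM (epsC) at -1.36 ± 0.27 (camera adjusted p = 5.1e-05, and adjusted p = 0.61 with an estimated correlation). The branched-chain amino acid and peptide genes repressed by CodY fell in 11 of 26 cases, 12 adjusted over the list alone, with ilvD at -1.21 ± 0.17 and ilvH at -1.20 ± 0.16 (camera adjusted p = 0.0038, and adjusted p = 0.61 with an estimated correlation). Of the extracellular protease genes, epr changed by -2.46 ± 0.32 and bpr by -2.36 ± 0.36. Over all genes 469 rose and 603 fell, and 567 rose and 529 fell with every array centred on its median. This count of 1072 depended on single arrays, with 216 genes without replicate 2 at 60 min, 351 without replicate 1 at 30 min and 673 without replicate 2 at 30 min, and it was 372 at an adjusted p under 0.01.

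From 60 to 120 min arginine synthesis genes and late spore genes rose. The carbamoyl phosphate synthase gene carB (BSU11240) rose by 5.61 ± 0.27, argD by 5.12 ± 0.26, argH by 4.62 ± 0.19 and argG by 4.40 ± 0.20. All 9 arginine synthesis genes rose, also adjusted over the list alone, by a median of 4.25 (camera adjusted p = 3.2e-11, and adjusted p = 0.65 with an estimated correlation). At 120 min 8 of these 9 genes, 8 adjusted over the list alone, were still below exponential growth, with a median of -1.25 (camera adjusted p = 0.15, and adjusted p = 0.68 with an estimated correlation). The gene yhfH rose by 4.91 ± 0.30. Late genes of the spore surface, cgeA, cgeB and cotG, rose by 4.89 ± 1.31, 4.74 ± 1.01 and 4.07 ± 1.27, and cotA, the coat laccase gene, by 2.90 ± 0.41. The late list had 15 of 31 genes up and 2 down, 16 and 2 adjusted over the list alone (camera adjusted p = 2.8e-04, and adjusted p = 0.65 with an estimated correlation). This call was lost with quantile normalization (adjusted p = 0.46). The mother cell list had 16 of 28 genes down and 1 up, 17 and 2 adjusted over the list alone, with spoIIIAG at -1.84 ± 0.20 (camera adjusted p = 0.0038, and adjusted p = 0.65 with an estimated correlation). All 11 fatty acid degradation genes rose again, also adjusted over the list alone, with ysiA (fadR) at 1.92 ± 0.29 (camera adjusted p = 2.1e-06, and adjusted p = 0.65 with an estimated correlation). Ribosomal protein genes rose in 29 of 50 cases, 33 adjusted over the list alone (camera adjusted p = 1.8e-08, and adjusted p = 0.65 with an estimated correlation).

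The largest decreases from 60 to 120 min were in the tyrosyl-tRNA synthetase gene tyrS at -3.79 ± 0.22, the pyruvate uptake gene ysbA at -3.58 ± 0.61, metE at -3.48 ± 0.18 and aroA at -3.31 ± 0.20. Aminoacyl-tRNA synthetase genes fell in 13 of 21 cases and rose in 1, with the same counts adjusted over the list alone (camera adjusted p = 2.8e-04, and adjusted p = 0.65 with an estimated correlation). Flagellar genes fell in 31 of 40 cases, 31 adjusted over the list alone, with fliD at -2.50 ± 0.29 (camera adjusted p = 8.6e-08, and adjusted p = 0.65 with an estimated correlation). Competence genes fell in 19 of 27, 21 adjusted over the list alone, with comGA at -2.94 ± 0.23 (camera adjusted p = 4.5e-08, and adjusted p = 0.65 with an estimated correlation). The biofilm matrix list fell in 13 of 15 genes, 13 adjusted over the list alone, with yveM (epsC) at -2.54 ± 0.27 (camera adjusted p = 3.1e-07, and adjusted p = 0.65 with an estimated correlation). The tricarboxylic acid cycle fell in 11 of 14 genes, 11 adjusted over the list alone, with citB at -1.29 ± 0.14 (camera adjusted p = 2.1e-04, and adjusted p = 0.65 with an estimated correlation). The mannose gene manP fell by a log2 change of -3.28 ± 0.41, the subtilosin gene sboA of -3.28 ± 0.16 and acoA of -2.66 ± 0.36. In the SigB list no gene of 40 passed limma's test, also when adjusted over the list alone, and the median of its members changed by 0.55 in replicate 1 and -0.50 in replicate 2. Camera did not call this list with all arrays (adjusted p = 0.55), but called it down without replicate 1 at 120 min and up without replicate 2 at 120 min. Over all genes 596 rose and 919 fell, a share risen of 39.3%, which became 60.1% with every array centred on its median. The count of 1515 became 790 without replicate 1 at 60 min, 790 when fitted on these 2 time points alone, 913 with array weights and 826 at an adjusted p under 0.01.

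**Figure D4:**
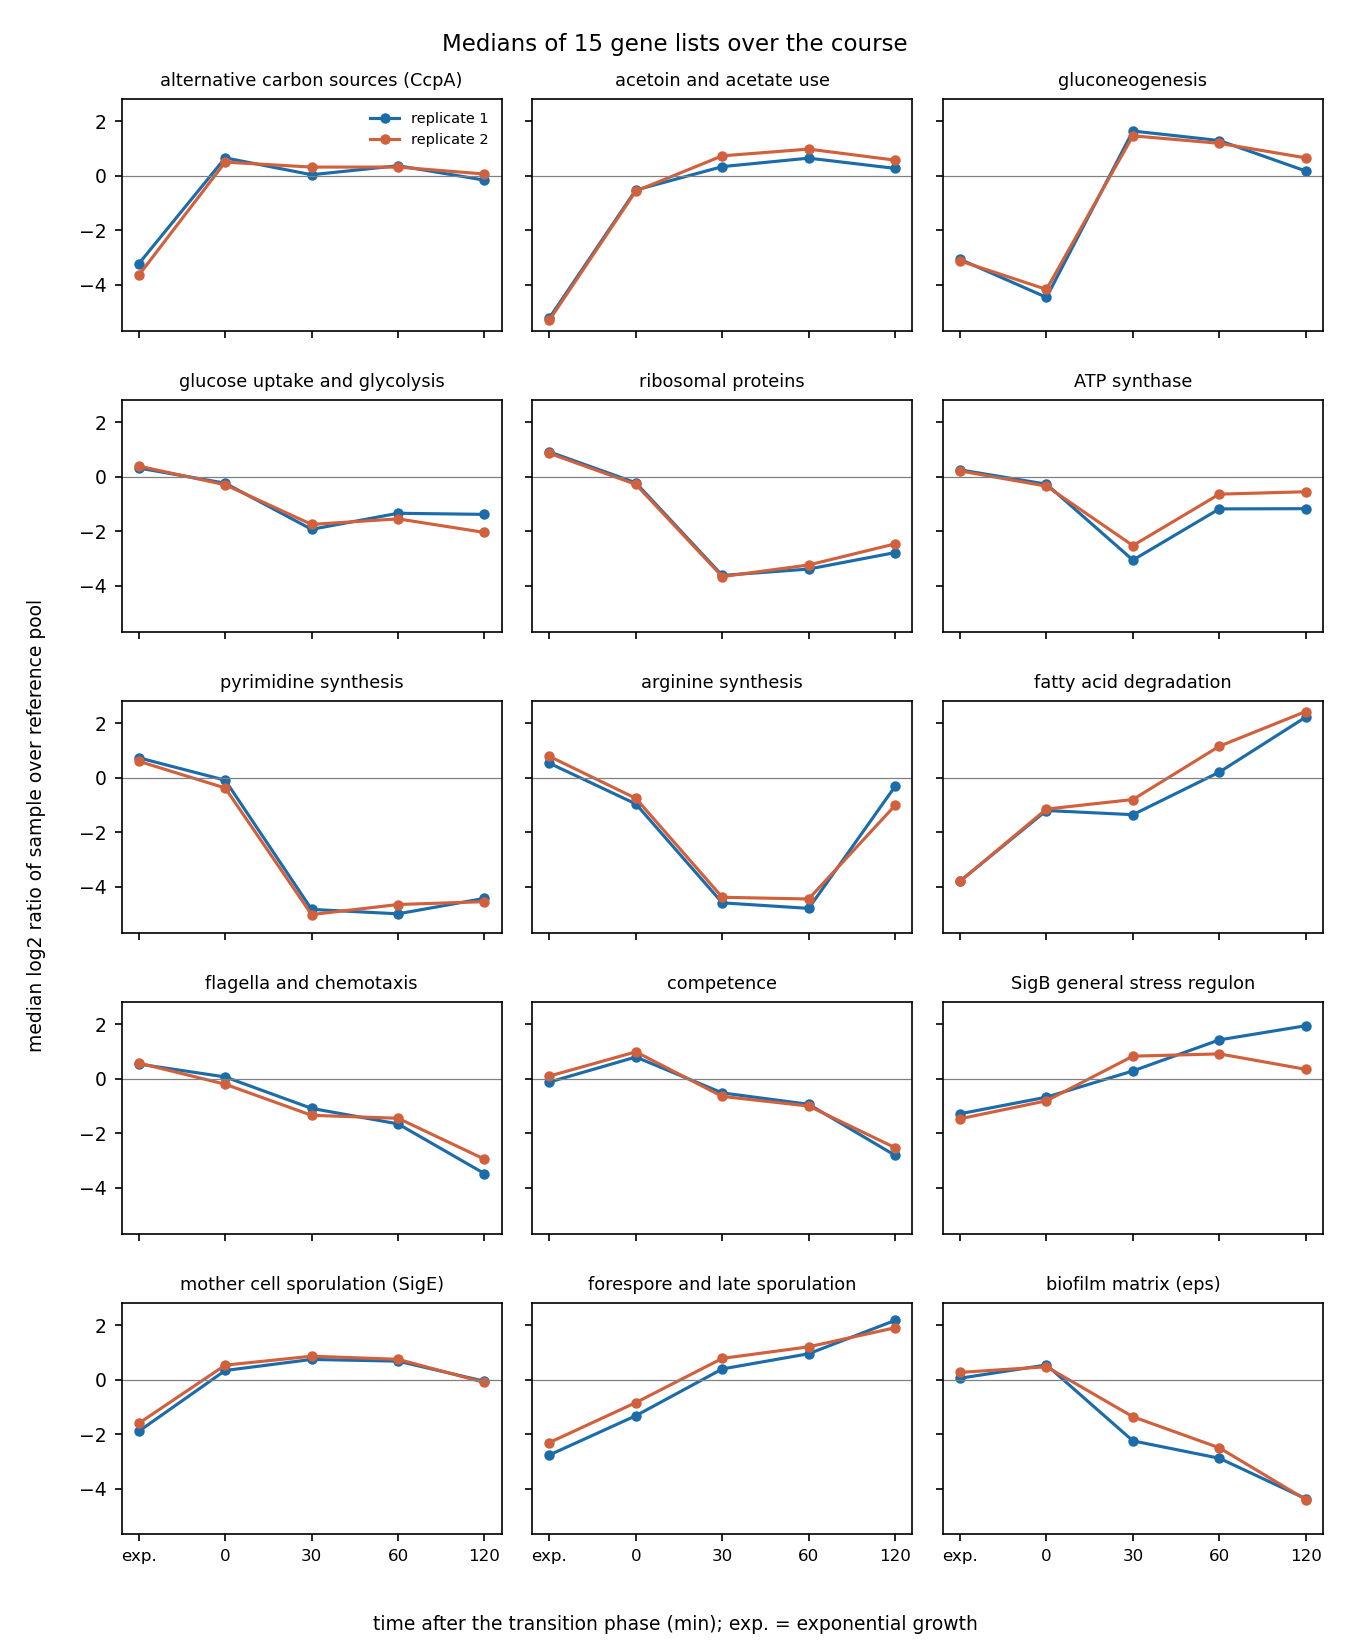
Median log2 ratio of sample over reference pool for 15 gene lists at the 5 time points, one line per replicate. The SigB list parts between replicates at 120 min (1.95 and 0.35), and the arginine synthesis list falls by 30 min and rises between 60 and 120 min, by a median of 4.25.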

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

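The count of changed genes at the transition, 2425 as reported, ranged from 1934 to 2673 when each array was left out in turn, the lone remaining array being assumed to vary like the other groups. For 30, 60 and 120 min against exponential growth these ranges were 3030 to 3421, 3006 to 3429 and 3162 to 3411. From the transition to 30 min it was 2325 to 3024, from 30 to 60 min 216 to 1514, from 60 to 120 min 790 to 1934, for the F test 3706 to 3937, and for the 163 list calls 157 to 174. The count from 30 to 60 min fell from 1072 to 372 and that from 60 to 120 min from 1515 to 826 at an adjusted p under 0.01, a stricter threshold. From 60 to 120 min the count was 913 with array weights, which gave both arrays at 120 min a weight of 0.36, and 790 with only the 2 time points in the fit, which holds fewer arrays. The list calls went from 163 to 0 with an estimated correlation between genes. The estimates included 0.0674 for overflow metabolism, 0.142 for alternative carbon sources, 0.437 for ribosomal proteins and 0.913 for the SigB list. These lie above the preset of 0.01, on which the list calls therefore depend. Whether this alone removed every call was not tested. Fry called 203, but it tests a list against no change and camera against the other genes, so these counts answer different questions.

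With quantile normalization 8 results at the transition turned their direction, to -0.51 for nhaX, -0.32 for ykzI, -0.04319 for yfhK, -1.29 for gapB (adjusted p = 0.000287), -0.09142 for hutU, -0.03003 for hutH, -0.107 for hutI and a median of -0.32 for the SigB list (adjusted p = 0.60). The cause was not tested. No other setting turned the direction of a result past the test. The SigB list from 60 to 120 min, which was not called, was called in opposite directions without replicate 1 and without replicate 2 at 120 min. Of 1197 named gene changes 1097 were past the test as reported, 1048 with quantile normalization, 1070 with centring, 1069 with array weights, 953 at an adjusted p under 0.01, and from 981 to 1093 with an array left out.

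The labels give replicates only a number. The correlations of replicate differences between time points ran from -0.21 to 0.39, and a replicate block gave 2448, 3297, 3313 and 3403 changed genes against exponential growth, 2838, 1158 and 1555 between successive times, 3846 in the F test and 163 list calls. Leaving out the genes with a value of exactly 1, chosen after seeing the data, kept every count within 3 genes. Averaging the series matrix per gene, medians over probes and a filter on dim features were not run, since its features carry no gene names and neither signals nor probe numbers are given in the sources used here. How far signal over background limits the values is therefore open.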

Other observations

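Genes for iron uptake under Fur fell early and stayed low, with 22 of 22 down at 30 min against exponential growth by a median log2 change of -3.60 (camera adjusted p = 2.0e-05, and adjusted p = 0.47 with an estimated correlation), among them the bacillibactin genes dhbB at -6.51 ± 0.47 and dhbC at -5.37 ± 0.47. The histidine use genes rose in all 6 cases, with hutH at 5.03 ± 0.47 and hutU at 4.82 ± 0.44 (camera adjusted p = 0.0062, and adjusted p = 0.47 with an estimated correlation). Genes of the prophage PBSX were up in 24 of 32 cases at the transition (camera adjusted p = 1.2e-04, and adjusted p = 0.52 with an estimated correlation) and down in 27 at 30 min, with xkdX at -2.64 ± 0.23 (camera adjusted p = 2.4e-04, and adjusted p = 0.47 with an estimated correlation). Phosphate starvation genes were up in 15 of 19 cases at 60 min, with the phosphate uptake genes pstS at 4.01 ± 0.21 and pstA at 3.36 ± 0.20 (camera adjusted p = 6.0e-05, and adjusted p = 0.44 with an estimated correlation). The bkd operon for branched-chain keto acids fell in all 8 genes from the transition to 30 min, with buk at -3.67 ± 0.44 and bkdAA at -3.27 ± 0.48 (camera adjusted p = 0.0032, and adjusted p = 0.56 with an estimated correlation). The toxin gene list under AbrB was split, with 7 up and 16 down of 23 at 60 min, and the immunity and regulator genes yvaZ (sdpI) and yvbA (sdpR) at 4.17 ± 0.43 and 4.50 ± 0.42.

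The 2 patterns below were found in the results, and all of their tests were chosen after seeing them. At 120 min the SigB genes were higher in replicate 1 than in replicate 2, by a median log2 difference of 1.67, or 3.18-fold, while histidine use genes differed the other way (-1.47) and 7 of the 29 genes over 4-fold apart were in the SigB list. A hypothesis of a scaling that varies with the ratio was excluded, since the difference was 1.42 above the median of 1000 random lists of other genes with like ratios (SD 0.0981), of which the highest was 0.568, while a scaling that varies with the signal was not tested. A wrong time label was also excluded, since the arrays correlated with r = 0.937 across genes and at most 0.831 with another time. Whether the cultures stood at different stages cannot be told, with a slope over the other genes of 0.117 of the replicate difference on the change from 60 to 120 min. A real difference between cultures was not tested.

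In exponential growth 8 late sporulation genes, cotX, cotV, yjcC, cgeC, cgeA, cgeB, sspG and cotG, chosen after their values were seen, were 4.71- to 13.6-fold higher in replicate 2, and all 8 were higher in replicate 2 at each of the 5 times. If the ratios are linear, the values argue against a mixing of RNA of the 120 min sample into the exponential one. These genes need shares from 0.984% to 12.7%, with a median of 1.91%, and 99% of the 100 most induced other genes allow less than that median. The upper limits of those other genes had a median of 0.727%. Whether the ratios are linear was not tested. A higher background of the exponential array could not be excluded. The 723 other genes of low ratio differed by a median of -0.000529 (SD 0.436), which shows no common rise among them. They were taken by a ratio of up to 0.455 in replicate 1, a limit set by sspG. The remaining late genes had ratios of at most 0.0861 there. A background acts on dim signals, and signals are not given. What raised these genes along the whole series of replicate 2 is open, and no biological explanation was tested.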
